A study of Homo sapiens with 12 samples.

How the data were processed

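MCF7 cells were treated for 6 hours with doxorubicin or DMSO, and total RNA was extracted with Trizol and labelled with biotin for whole-transcript exon arrays, per the labels' protocols. The deposited gene-level table holds linear intensities per transcript cluster, as its values show: they are never negative and reach 18023. The deposited exon-level table holds log2 intensities per probe set, with array medians between 7.19 and 7.44. Affymetrix Power Tools, RMA (a background correction, normalization and summary method for such arrays) and the genome build hg18 are named in the submitters' processing notes, with no versions or roles. Which of these steps made each table, and whether the arrays were scaled to each other, is not given in the sources used here. Array medians differed in both tables, so a change in the level of all genes and a difference in scaling cannot be separated.

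Each array had its own column, mapped through its sample record, and 0 columns were left unmapped. Groups came from the agent and title of each record. Clusters and probe sets were named through a platform annotation. Of 22011 clusters, 14432 had 1 gene symbol, 2408 several and 5171 none, and of 287329 probe sets, 261273 had 1 symbol, 9155 several and 16901 none. Symbols were updated through Entrez identifiers to a RefSeq gene table of another genome build, GRCh38.p14, which held 14404 of the 14432 single-symbol clusters and which was used only for names, gene lengths and neighbours. Features with several symbols or none were tested and not named. No genome was used here, so no coordinates are printed and the position of a probe set inside its gene was not analysed here.

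The gene-level intensities were tested as log2(intensity + 1), without a filter on dim clusters, and fold changes are on that scale, which understates the change of dim genes. Exon-level log2 values were used as deposited. Both were fitted with lmFit and eBayes in limma 3.58.1 under R 4.3.3, doxorubicin against control, two-sided, with no covariate and Benjamini-Hochberg adjustment over all features at a threshold of 0.05. Usage of a probe set was tested with diffSplice in limma, which compares its log2 fold change with that of the other probe sets of the gene and shares 1 variance among them. It ran on probe sets at or above the 33rd percentile of mean log2 intensity (6.27) in genes with at least 3 of them. As an alternative chosen after seeing the data, the same difference was tested in limma with the own spread of each probe set. Gene lists were tested with camera in limma at a preset correlation of 0.01, adjusted over 25 lists, and also with an estimated correlation. A list member was represented by its brightest cluster. Calls of probe sets in a list were compared with all genes tested by Fisher's exact test.

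The lists, the tests and the rule for naming genes were fixed before the data were examined. Besides those described in the results, lists covered NF-kB targets, interferon-stimulated genes, ribosomal proteins, ribosome biogenesis, heat shock proteins, apoptosis regulators and sterol synthesis. The naming rule took the 12 largest rises and 12 largest falls among called single-symbol clusters whose arrays did not overlap between groups and whose higher group lay at or above the median intensity. It further named up to 4 called members of each list, or the member with the smallest p where none was called, and CDKN1A, MDM2, TP53, TOP1, TOP2A, TOP2B, MYC and ESR1. For usage it named the 6 largest gains and 6 largest losses without overlap of the arrays, and the probe set with the smallest adjusted p in each gene of a list of damage-responsive splicing.

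The tests were run on simulated data with the means of the real arrays and the variances that limma had moderated. For the gene-level and exon-level tests, changed features were drawn only from those at or above the median intensity. Recovery of dimmer ones was therefore not measured in these tests. In the gene-level test, 35% of clusters changed by 1 on the log2 scale and 89% of those changed by 2 were recovered, with 9 false calls among 22011. In the exon-level test, 0% and 75% of probe sets were recovered for changes of 1 and 2, with 8 false calls among 287329. The shared-spread usage test recovered 37% and 97% with 213 false calls among 173758, and the own-spread test 2% and 83% with 5. A list of 36 genes shifted by 0.5 was recovered by camera, with 0 false lists. The simulated genes were independent, whereas the estimated correlation of real lists reached 0.81. The simulation therefore does not give the rate of false lists on the real arrays. No replicate pair held identical tables: the SD of the difference between replicates was 0.41 to 0.69 on the log2 scale at the gene level.

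Alternatives comprised leaving out each array in turn, the replicate number as a block, quantile normalization, median centring, a filter on dim features, other variance models, array weights, a size threshold, gene values averaged from exon-level probe sets, a splicing index and other cluster or class definitions. Chosen after seeing the data were an offset of 16, testing only clusters with 1 symbol, an estimated correlation after quantile normalization or without each array, the own-spread usage test, and the excess of usage calls in a list without each array, after quantile normalization and in matched draws.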

Results

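RNA was measured in MCF7, an oestrogen receptor-positive human breast cancer line, after 6 hours with doxorubicin at 2 µg/ml or with 0.1% DMSO as the control. Doxorubicin is an anthracycline that intercalates into DNA and traps topoisomerase II on it. Each condition had 3 arrays of the Affymetrix human exon type, whose probe sets lie along exons and are also summarised into transcript clusters, which stand for genes. The 12 sample records describe these 6 arrays at both levels, so the gene-level and exon-level results below are not independent. The median intensity per transcript cluster was 197, 195 and 177 in the control arrays and 166, 173 and 172 in the doxorubicin arrays. The number of arrays limits the precision of every value. The labels do not say that replicates came from separate cultures, so each p-value measures the spread between these samples, which may be technical. The series title concerns alternative terminal exons and cell cycle regulation by topoisomerase inhibitors, and doxorubicin was compared with control for gene levels and for single exons.

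At the gene level, several linker and core histone genes, a set of short-lived regulators and the luminal transcription factor GATA3 fell in doxorubicin, and a smaller number of genes, including some that were dim in control cells, rose. Of 22011 transcript clusters, 1059 fell and 94 rose in limma at an adjusted p under 0.05. Clusters without a gene symbol made up 806 of the falls and 18 of the rises, whereas 213 falls and 62 rises belonged to clusters with 1 symbol. Of the latter, 112 fell and 34 rose by at least 2-fold. The 3 doxorubicin arrays lay entirely above or below the 3 control arrays in 5681 clusters (25.8%, against 10% by chance), and did so for every called gene named below. The exon-level probe sets of the same genes were then examined: the median probe set moved in the same direction for 188 of the 197 fallen and all 57 of the risen genes that had 3 or more probe sets. That median change reached 1.5-fold in 145 of the fallen and 45 of the risen genes. Of all probe sets 61.6% were higher in doxorubicin, and both levels rest on the same arrays.

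The histone genes of S phase, which supply nucleosomes during DNA replication, had the largest median shift of the 25 lists. Of 41 measured, 9 fell, 0 rose and 32 did not pass the test over all clusters. Adjusted over the list alone, 33 fell and 1 rose, the linker histone H1-1 (log2 1.20), a gene picked out after its value was seen. Their median log2 fold change was -1.83, and 39 of 41 values were lower. The linker histone H1-2 had a mean intensity of 1503 ± 322 (SD, n = 3) in control and 259 ± 65.2 (SD, n = 3) in doxorubicin, which was 5.84-fold lower (log2 -2.55 ± 0.25 SE, adjusted p 0.0053). H1-5 was 6.76-fold lower (adjusted p 0.023), H3C12 7.69-fold lower (adjusted p 0.017) and H2BC8 5.1-fold lower (adjusted p 0.021). H1-3, H1-4, H3C1 and H2BC14, and H2AC12 from outside the list, also stood among the 12 largest falls of single-symbol genes that reached the median intensity of all clusters in either condition, between 5.02-fold and 8.07-fold. Histone genes are near-identical in sequence, so a probe can read more than its own gene. The list passed camera with a preset correlation (adjusted p 1.06e-27), and its adjusted p was 0.68 with an estimated correlation. The number of fallen histone genes was 3 without control replicate 1, 1 without control replicate 2, 3 without control replicate 3 and 16 without doxorubicin replicate 1.

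Short-lived transcripts were covered by a pair of lists. Among 32 immediate early genes, which respond to growth signals within minutes, 8 fell and 0 rose, with a list median of -0.25. Adjusted over the list alone, 9 fell. MYC, a transcription factor that drives growth, dropped from an intensity of 2440 ± 209 to 892 ± 216 (SD, n = 3 each), which was 2.78-fold lower (adjusted p 0.014). IER3, JUNB and the mRNA decay factor ZFP36 fell 3.39-fold, 2.32-fold and 2.01-fold (adjusted p 0.014, 0.012 and 0.016). FOS and EGR1, picked out after their values were seen, had log2 fold changes of -0.06 and 0.11 and did not pass. Of 21 circadian and short-lived transcription regulators, 5 fell and 0 rose, with a median of -0.16, and adjusted over the list alone 6 fell. ID3 and ID1, which block the DNA binding of helix-loop-helix factors, were 4.46-fold and 4.31-fold lower (adjusted p 0.0049 and 0.0092). BHLHE40, a repressor in the circadian clock, was 2.14-fold lower (adjusted p 0.0097) and SOX4 1.52-fold lower (adjusted p 0.033). The fifth, IRF2BP2, outside the naming rule and picked out after its value was seen, was 1.79-fold lower (adjusted p 0.037). Both lists passed camera with a preset correlation (adjusted p 7.39e-08 and 0.00022), and for both the adjusted p was 0.68 with an estimated correlation. Fallen immediate early genes numbered 3 without control replicate 1, 0 without control replicate 2, 5 without control replicate 3 and 4 without doxorubicin replicate 3. Fallen circadian and short-lived regulators numbered 1 without control replicate 2 and 3 without control replicate 1 or any single doxorubicin replicate.

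KRAB zinc finger genes are a large family of DNA-binding repressors. Of 47 measured, 7 fell, 0 rose and 40 did not pass, and 45 had lower values, with a median of -0.62. Adjusted over the list alone, 28 fell. ZNF180 was 2.69-fold lower, ZNF84 2.10-fold, ZNF226 2.06-fold and ZNF155 1.89-fold (adjusted p 0.034, 0.025, 0.023 and 0.033). The list passed camera with a preset correlation (adjusted p 4.23e-22), and its adjusted p was 0.68 with an estimated correlation. The number fallen was 1 without control replicate 1, 0 without control replicate 2 or doxorubicin replicate 2, 12 without control replicate 3, 3 without doxorubicin replicate 1 and 2 without doxorubicin replicate 3.

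**Figure D1:**
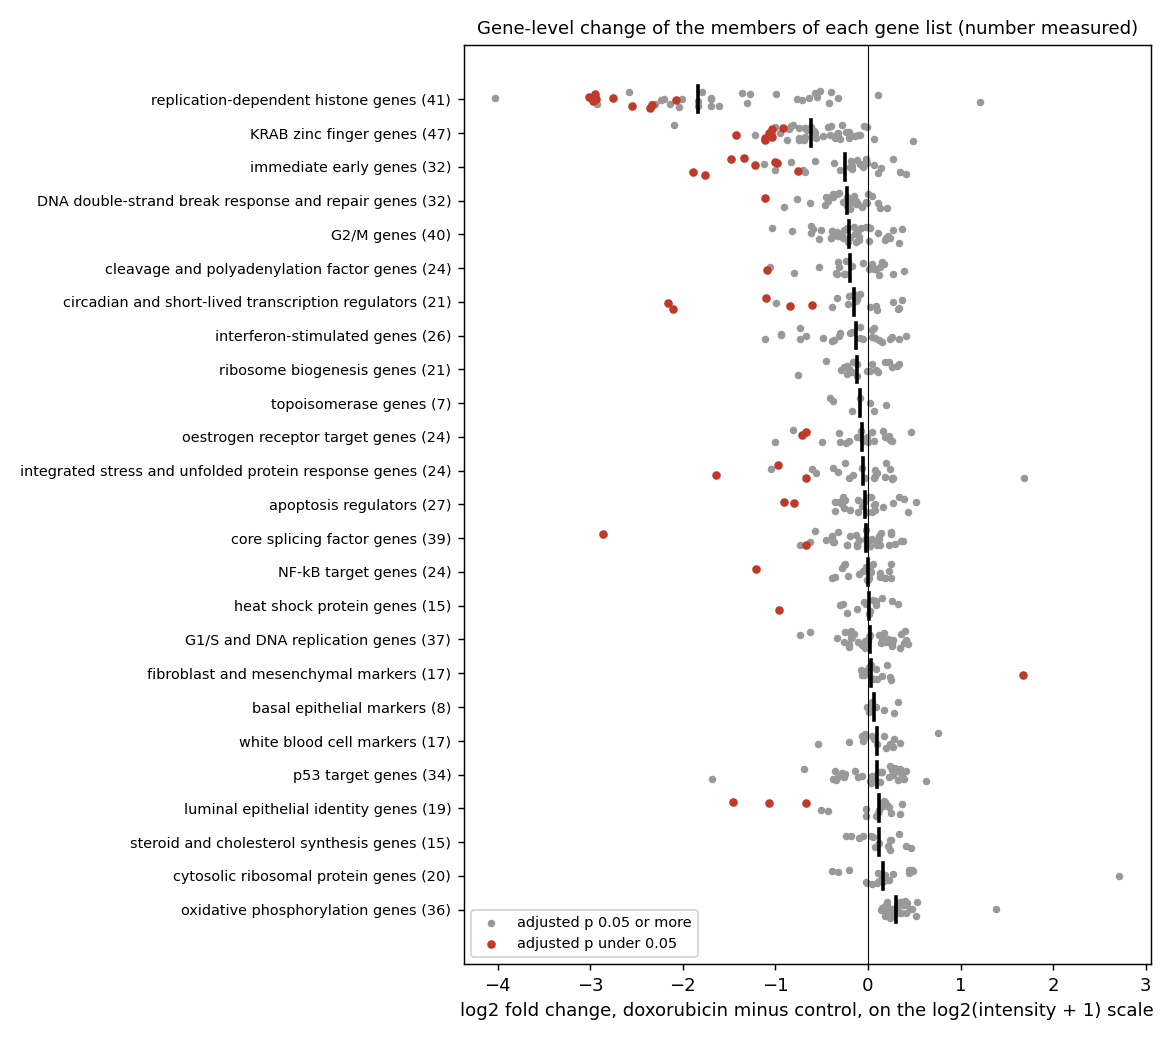
Each point is a measured member of a fixed gene list, with its gene-level log2 fold change (doxorubicin minus control, 3 arrays each) on the x axis and the lists on the y axis with their number of measured members; black bars mark list medians and red points have a limma adjusted p under 0.05. The histone list has a median of -1.83 with 9 red points, the KRAB zinc finger list a median of -0.62 with 7, and the oxidative phosphorylation list a median of 0.30 with 0.

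The p53 target genes did not pass the list test. p53 is the transcription factor that DNA damage activates, and its targets halt the cell cycle or start apoptosis. Of 34 measured, 0 rose and 0 fell in limma, also when adjusted over the list alone, with a median of 0.10 and a camera adjusted p of 0.84 (adjusted p 0.96 with an estimated correlation). At an unadjusted p under 0.05, 2 were higher and 2 lower. The list median was 0.19 after quantile normalization, 0.25 after median centring, 0.23 without control replicate 1 and -0.02 without control replicate 3, and camera passed with none of the 6 arrays left out. The cell cycle inhibitor CDKN1A read 694 ± 101 in control and 632 ± 111 in doxorubicin (SD, n = 3 each), a log2 fold change of -0.14 with a 95% interval of -0.59 to 0.31, and 0.01 after median centring of the arrays. MDM2, the ubiquitin ligase that p53 induces and that degrades p53, had -0.34 with an interval of -0.71 to 0.02. PLK2 had the smallest p of the list, at -1.69 (adjusted p 0.057, and 0.049 after quantile normalization and 0.016 without doxorubicin replicate 1 for gene PLK2). For 31 of the 34 genes the 95% interval excluded a 2-fold rise, and for 27 after quantile normalization and 28 after median centring. TP53 was not analysed here.

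Genes of the cell cycle and of DNA repair showed small values. None of 40 G2/M genes passed in limma (6 lower and 1 higher at an unadjusted p under 0.05; 3 fell without control replicate 3), although 30 were lower; their median was -0.20 and the list passed camera (adjusted p 0.00049; adjusted p 0.68 with an estimated correlation). The kinetochore gene NDC80 had the smallest p among them, with a log2 fold change of -1.04 (adjusted p 0.12). After median centring of the arrays that list median was -0.05, and it was -0.02 without control replicate 1 and -0.35 without control replicate 3. Without control replicate 1 the camera adjusted p of the G2/M list was 0.32. Among 37 G1/S and DNA replication genes 0 passed in limma (1 lower and 2 higher at an unadjusted p under 0.05), with a median of 0.03 and a camera adjusted p of 0.84 (adjusted p 0.96 with an estimated correlation, and camera adjusted p 0.041 without control replicate 1). The G1/S median was 0.09 after quantile normalization, 0.18 after median centring or without control replicate 1, and -0.11 without control replicate 3, and 1 gene fell after quantile normalization or without control replicate 3. Of 32 genes of double-strand break response and repair, 1 fell, both over all clusters and over the list alone: PALB2, which links BRCA1 to BRCA2, was 2.17-fold lower (adjusted p 0.031). It kept its call without control replicate 1 or control replicate 3 only; 2 genes of the list fell without control replicate 3 and 0 without control replicate 2 or any single doxorubicin replicate. That list had a median of -0.22, or -0.13 without control replicate 1 and -0.38 without control replicate 3. It passed camera (adjusted p 7.3e-06, and adjusted p 0.68 with an estimated correlation). Among 7 topoisomerase genes 0 passed in limma (1 lower at an unadjusted p under 0.05). Their list median was -0.08, or 0.07 after median centring, 0.04 without control replicate 1 and -0.34 without control replicate 3. The camera adjusted p was 0.26 (adjusted p 0.72 with an estimated correlation, and camera adjusted p 0.032 without control replicate 3). TOP2A and TOP2B, the targets of doxorubicin, had log2 fold changes of -0.38 ± 0.20 and 0.02 ± 0.21 (SE), the latter -0.04 after quantile normalization. TOP1 was covered at the gene level only by clusters with several symbols, and the median of its 27 exon-level probe sets was 0.14.

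In the luminal epithelial list, 3 of 19 genes fell and 0 rose, and 4 fell when adjusted over the list alone, the fourth being FOXA1 (log2 -0.51, picked out after its value was seen). GATA3, which specifies luminal breast cells, dropped from 2790 ± 467 to 1012 ± 94.2 (SD, n = 3 each), which was 2.74-fold lower (adjusted p 0.0073). XBP1, a transcription factor of the unfolded protein response, was 1.59-fold lower and the tight junction gene CLDN4 2.10-fold lower (adjusted p 0.023 and 0.046). Fallen luminal genes numbered 2 after median centring or without control replicate 3, and 1 without control replicate 1, control replicate 2 or any single doxorubicin replicate. CLDN4 lost its call without each array in turn. The oestrogen receptor gene ESR1 had a log2 fold change of -0.02 ± 0.17 (SE), or 0.13 after median centring. The luminal list had a median of 0.12. Of 24 oestrogen receptor targets 2 fell, on either adjustment: XBP1 and the receptor cofactor NRIP1, which was 1.64-fold lower (adjusted p 0.046). Fallen targets numbered 0 after median centring and 0 without control replicate 1, control replicate 2, doxorubicin replicate 2 or doxorubicin replicate 3, and 1 without control replicate 3 or doxorubicin replicate 1. NRIP1 lost its call without each array in turn, and XBP1 kept its call in only 1 of these 6 settings. The 2 genes therefore do not account for both of the last counts. The median of these targets was -0.06, or 0.003 after quantile normalization and 0.09 after median centring. Neither list passed camera (adjusted p 0.43 for the luminal list and 0.13 for the targets, and adjusted p 0.68 for both with an estimated correlation), although the targets had a camera adjusted p of 0.012 without doxorubicin replicate 1, and both lists passed after quantile normalization, as lower than other genes (camera adjusted p 0.028 and 0.0035, and 0.33 for both with an estimated correlation). In limma, 0 of 8 basal, 0 of 17 white blood cell and 1 of 17 fibroblast markers passed, with list medians of 0.07, 0.10 and 0.04 (at an unadjusted p under 0.05, 0, 2 and 1 were higher). None of these 3 lists passed camera (adjusted p 0.26, 0.24 and 0.31, and adjusted p 0.68 for all with an estimated correlation), although white blood cell markers had 0.036 without control replicate 3. After quantile normalization the medians were 0.23, 0.26 and 0.21, 0 basal, 2 white blood cell and 2 fibroblast markers rose, and the camera adjusted p was 0.19, 0.068 and 0.028 (0.37, 0.41 and 0.37 with an estimated correlation), and after median centring the medians were 0.22, 0.25 and 0.19. The fibroblast marker FAP (adjusted p 0.025) had mean intensities of 13.4 ± 1.45 and 46.8 ± 17, both below the lower quartile of every array (57.8 at the lowest), so no fold is given. It lost its call without any single control array or doxorubicin replicate 1.

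Oxidative phosphorylation was the 1 list past camera with higher values when all arrays were used as deposited, with the preset correlation alone (adjusted p 2.36e-05, against 0.68 with an estimated correlation). All 36 measured genes, which encode subunits of the mitochondrial respiratory chain and ATP synthase, had higher values in doxorubicin, with a median of 0.30, and 0 passed singly in limma (2 higher at an unadjusted p under 0.05). NDUFB3 came closest (adjusted p 0.051), with mean intensities of 13.4 and 34.9, too dim for a fold to be given, and rose after quantile normalization, after median centring and without control replicate 2 (adjusted p 0.021, 0.026 and 0.047 for gene NDUFB3). Without control replicate 3 or doxorubicin replicate 1 the median was 0.13, and without control replicate 1 it was 0.46. Without doxorubicin replicate 1 the camera adjusted p was 0.053. Ribosomal protein genes had higher values with a camera adjusted p of 0.028 without control replicate 2 and 0.027 without doxorubicin replicate 3, and sterol synthesis genes with 0.029 without control replicate 2.

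Stress response and RNA processing genes held single changes. Of 24 integrated stress and unfolded protein response genes, 3 fell: the stress transcription factor ATF4 was 1.96-fold, XBP1 1.59-fold and the mTORC1 inhibitor DDIT4 3.11-fold lower (adjusted p 0.012, 0.023 and 0.040). The number fallen was 1 without control replicate 1 or doxorubicin replicate 3, 0 without control replicate 2, and 2 without control replicate 3 or the other doxorubicin replicates. The median log2 fold change of the 13 exon-level probe sets of ATF4 was -0.19 and only 1 of them fell. Its gene-level fall may therefore not stand for the whole gene. Adjusted over the list alone, 5 fell and 1 rose; TRIB3, CHAC1 and the riser PSAT1 were picked out after their values were seen. TRIB3 and CHAC1 had log2 fold changes of -0.57 and -1.05, and PSAT1 was too dim for a fold to be given (mean intensities 14.1 and 43.5). The median of the stress list was -0.05, or 0.10 after median centring, -0.20 without control replicate 1 and 0.09 without control replicate 2. Its camera adjusted p was 0.038 (adjusted p 0.68 with an estimated correlation). Without control replicate 2, control replicate 3 and doxorubicin replicate 1 the camera adjusted p was 0.34, 0.16 and 0.25. Of 39 core splicing factors, 2 fell, on either adjustment: SRSF10, a regulator of exon choice, and the RNA helicase DDX17, which was 1.60-fold lower (adjusted p 0.022). Only 3 of the 36 exon-level probe sets of SRSF10 fell, so its gene-level fall may not stand for the whole gene. DDX17 kept its call only without control replicate 3, and otherwise 1 gene of the list fell when an array was left out. The splicing factor list had a median of -0.02, or 0.13 after median centring, and a camera adjusted p of 0.038 (adjusted p 0.68 with an estimated correlation). Without control replicate 1, control replicate 2 and doxorubicin replicate 3 the camera adjusted p was 0.32, 0.061 and 0.063. Of 24 cleavage and polyadenylation factors, 1 fell: CSTF2T, a subunit of the cleavage stimulation factor, was 2.13-fold lower (adjusted p 0.011), and 0 fell without control replicate 2. Adjusted over the list alone 3 fell, with CSTF1 and PCF11, picked out after their values were seen, at -0.79 and -1.06. That list had a median of -0.19, or -0.06 without control replicate 1 and -0.31 without control replicate 3. Its camera adjusted p was 0.012 (adjusted p 0.68 with an estimated correlation), or 0.31 without control replicate 1.

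**Figure D2:**
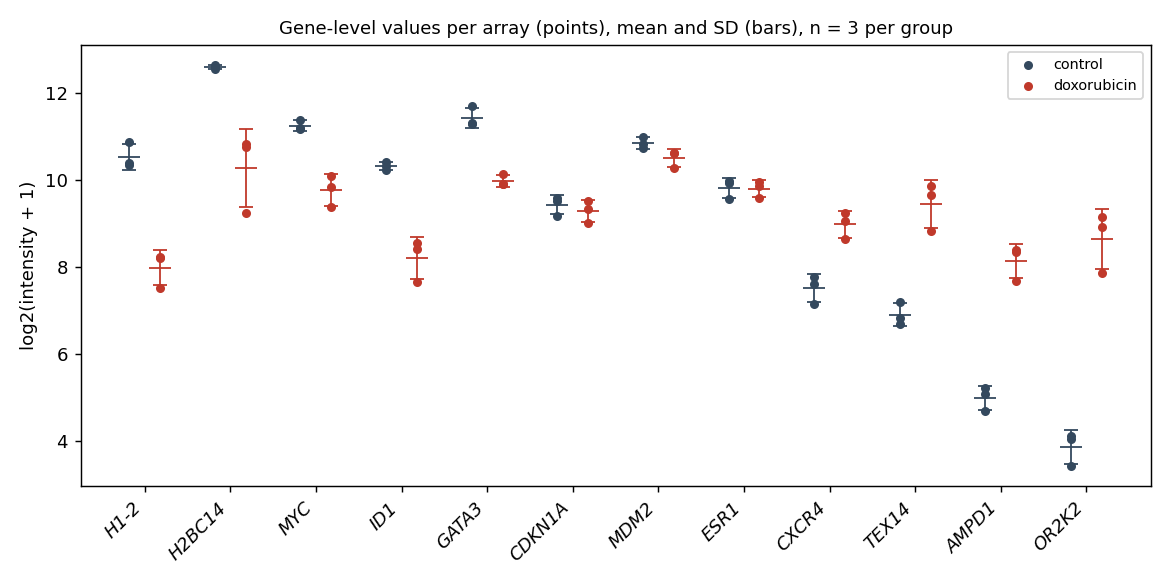
Points are the gene-level values of single arrays on the log2(intensity + 1) scale, with the mean and SD of the 3 control and 3 doxorubicin arrays, for 12 of the named genes on the x axis. H1-2, H2BC14, MYC, ID1 and GATA3 are lower in doxorubicin, CXCR4, TEX14, AMPD1 and OR2K2 are higher, and the CDKN1A and ESR1 arrays of the 2 conditions overlap.

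The 12 largest rises were taken among single-symbol genes that reached the median intensity of all clusters in either condition; some dimmer genes, not named here, rose more. Their control intensities ranged from 13.9 in OR2K2 and C17orf47 to 299 in GTF3C6 and SEC61A2. OR2K2, an olfactory receptor gene, went from an intensity of 13.9 ± 3.61 to 427 ± 173 (SD, n = 3 each), a log2 fold change of 4.78 ± 0.37 (SE, adjusted p 0.0033). AMPD1, which encodes the AMP deaminase of muscle, rose from 31.4 to 288 (adjusted p 0.0033), C17orf47 from 13.9 to 227 and STPG4 from 48.3 to 217. The control intensities of these 4 lay below the lower quartile of every array, so the size of their rises depends on the offset: the log2 fold changes of gene OR2K2, gene C17orf47, gene AMPD1 and gene STPG4 were 4.78, 3.87, 3.14 and 2.11, and with an offset of 16 they were 3.81, 2.96, 2.66 and 1.83. TEX14, a germ cell gene, rose 5.83-fold (adjusted p 0.0089) and LINC00310 3.50-fold. The cluster numbers of C17orf47 and TEX14, 3764581 and 3764592, lie close together, so these rises may not be separate. The chemokine receptor gene CXCR4 rose from 185 ± 39.8 to 515 ± 107 (adjusted p 0.021). LSMEM1, SLIRP-OT1, GTF3C6, AP4S1 and SEC61A2 completed these 12, between 1.72-fold and 2.35-fold. At the exon level, 26 of 40 probe sets of TEX14, 11 of 15 of AMPD1 and 3 of 3 of OR2K2 rose. KPNA2 and SRSF10, the largest falls outside the histones among single-symbol genes eligible under the naming rule, had few probe sets past the exon-level test. KPNA2, a nuclear import receptor, went from 516 to 46.7 in its gene-level value (adjusted p 0.00066), and yet the median of its 27 exon-level probe sets was -0.03 and only 1 of them fell. Its cluster 4041113 went from log2 9.01 to 5.57, close to probe set 4041140 alone (8.94 to 5.79). That probe set lay 3.51 below the mean of its gene's tested probe sets in controls, so the cluster value may not stand for KPNA2. SRSF10 was 7.24-fold lower in its cluster 4045780 (adjusted p 0.0028), with a median of -0.08 over 36 probe sets, of which 3 fell. Those probe sets carry numbers from 4044415 to 4044447 and from 4045792 on. Whether both ranges belong to that cluster is not known, so its value may not stand for all of SRSF10. EID3 went from 313 to 57.7 (adjusted p 0.014). The doxorubicin values of KPNA2 and EID3 also lay below the lower quartile of every array; the log2 fold changes of gene KPNA2 and gene EID3 were -3.45 and -2.45, and with an offset of 16 they were -3.09 and -2.16.

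Whether the deposited gene-level values had been scaled between the arrays is not known. Quantile normalization moved the median log2 fold change of all clusters from 0.02 to 0.14 and gave 1086 falls and 439 rises, and median centring moved it to 0.17 and gave 947 and 214. After quantile normalization 18 lists passed camera with the preset correlation in place of 10, and 0 passed with an estimated one on either set of values or without any 1 array. The further ones were the interferon, oestrogen receptor target, luminal, ribosome biogenesis, heat shock, apoptosis and topoisomerase lists, all lower than other genes, and the fibroblast list, higher than other genes. The list medians moved from -1.83 to -1.65 and -1.68 for histones, from -0.62 to -0.51 and -0.47 for KRAB zinc finger genes, from -0.25 to -0.16 and -0.10 for immediate early genes, and from 0.30 to 0.31 and 0.45 for oxidative phosphorylation. Those of the circadian and short-lived regulators became -0.10 and -0.005, of double-strand break repair genes -0.18 and -0.07, and of cleavage and polyadenylation factors -0.12 and -0.04. Calls numbered 439 without control replicate 1 and 248 without control replicate 2, where 30 and 40 named genes lost their call. Without control replicate 3 and doxorubicin replicates 1, 2 and 3, 19, 12, 21 and 19 lost theirs. Rises numbered 26 without control replicate 1, 17 without control replicate 2, and 26 without doxorubicin replicate 2 or doxorubicin replicate 3. OR2K2, C17orf47, AMPD1, TEX14, STPG4, KPNA2, SRSF10, H1-2, GATA3 and ID3 kept their call without any single array.

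At the level of single probe sets, the clearest blocks of change lay in PPP1R10, a nuclear regulatory subunit of protein phosphatase 1, with 16 of 27 probe sets lower, and in TEX14 and AMPD1, which rose. PPP1R10, SEPTIN4, SRSF2, SF1 and LUC7L3 are named here after their values were seen. Among splicing genes, 5 of 35 probe sets of SF1, 5 of 27 of LUC7L3 and 4 of 16 of SRSF2 fell. GATA3 had 5 of 13 lower, and SEPTIN4 7 of 36 higher. Of 287329 probe sets, 694 fell and 217 rose in limma, in 196 and 99 genes, and 0 genes had both. Calls numbered 0 without control replicate 1 or control replicate 2, 1 without doxorubicin replicate 2, 122 without doxorubicin replicate 3 and 468 without doxorubicin replicate 1. Rises numbered 103 without control replicate 3.

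Use of single probe sets was compared next, as the change of a probe set against the other probe sets with the same gene symbol. Without their positions, this comparison does not by itself single out alternative exons. Most calls were losses of usage, though with the gene-level value as reference (a splicing index) 58 were losses and 76 gains, and 46 of the 367 genes with such a probe set were also called at the gene level. A probe set of RBM8A, a core protein of the exon junction complex, had a usage difference of -3.87 ± 0.42 on the log2 scale against the rest of its gene (SE from its own spread, n = 3 per group). Single probe sets of NCOA5, a receptor coactivator, RPL37A, a ribosomal protein, SLC25A36, ASPH and KPNA2 had usage differences of -3.25, -3.03, -2.99, -2.95 and -3.14. Probe sets were grouped by symbol, so the KPNA2 loss may be a difference between clusters and not in exon usage. In doxorubicin the probe sets of RBM8A, NCOA5 and SLC25A36 read log2 5.07, 4.90 and 4.58. These lay below the lower quartile of every exon-level array (5.50 at the lowest). Those of ASPH and KPNA2, at 5.54 and 5.79, lay below the filter of 6.27. The sizes of these losses are therefore uncertain. Of the 104 gains, 67 were probe sets that themselves rose by more than 1.5-fold. Gains of usage were led by SEPTIN4 at 2.11 ± 0.18, PPP1R3C, a glycogen-targeting subunit of protein phosphatase 1, at 2.01 ± 0.20, though its own log2 fold change was 0.15 and another of the gene's 3 tested probe sets fell by 2.49, and PNLDC1 at 1.83 ± 0.19 (SE from the own spread). These 9 passed both with the spread shared within a gene and with the own spread of each probe set, the latter at an adjusted p between 0.0011 and 0.025. MOB4, TEX14 and LAMB4 had usage differences of 2.06, 2.04 and 1.91 and passed only with the shared spread, at 0.0047, 0.00047 and 0.00092, against 0.23, 0.13 and 0.055 with their own spread. In controls the gaining probe sets of SEPTIN4, PNLDC1, MOB4, TEX14 and LAMB4 read log2 6.12, 5.07, 5.47, 4.63 and 5.69. These lay below the filter of 6.27, which they passed only through their doxorubicin values, so the filter favoured such gains. Probe set 3764588 of SEPTIN4 lies in number between the risen clusters 3764581 of C17orf47 and 3764592 of TEX14. Its gain may therefore not be separate from theirs.

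A larger share of splicing factor genes than of all genes had at least 1 such probe set. With the shared spread, 10 of 45 core splicing factors had a call, among 367 of 13376 genes (2.74%), and Fisher's exact test over the genes tested, one-sided, gave an adjusted p of 7.25e-06 over 25 lists. With the own spread, 4 had a call, SRSF1, SRSF2, SRSF10 and EWSR1, among 84 genes (adjusted p 0.0044). Splicing factors had a median of 16 tested probe sets and all genes 10. In 10000 random draws of genes matched for that number, a test chosen after seeing the data, the mean count was 1.73 against 10 with the shared spread (adjusted p 0.0025) and 0.37 against 4 with the own spread (adjusted p 0.018). Without control replicate 2 the excess did not pass with the shared spread (4 genes, adjusted p 0.061), and with the own spread it passed only without control replicate 1 (adjusted p 0.045) among the 6 arrays left out, with 0 genes called without control replicate 2 or doxorubicin replicate 2. In SRSF2, 4 probe sets with consecutive numbers had usage differences between -2.61 and -1.34, all past both tests. In SRSF10, 3 consecutive probe sets past both tests had usage differences between -2.53 and -1.93, with a neighbour at -1.70 past the shared-spread test alone. The probe sets of SRSF10 carry numbers from 4044415 to 4044447 and from 4045792 on, and these 3 lay in the later range. Probe sets were grouped by symbol, so the SRSF10 losses may be a difference between clusters and not in exon usage. In SF1, which binds the branch point and lies outside the fixed lists, 4 consecutive probe sets past both tests had usage differences between -2.18 and -1.70, and the next, past the shared-spread test alone, -2.63. Immediate early genes also had an excess of calls with the shared spread (5 of 36, adjusted p 0.035), which was lost whichever array was left out and after quantile normalization (adjusted p 0.20) but passed in the matched draws (adjusted p 0.0038), and 0 had a call with their own. Among 21 tested genes known for splicing that responds to DNA damage, 4 had a probe set past the shared-spread test. EWSR1 had a usage difference of -1.53, DDX17 -1.09, TAF6 -1.27 and TRA2B -1.45. With the own spread the adjusted p was 0.024 for EWSR1 and 0.099, 0.29 and 0.44 for the others. Without control replicate 2, EWSR1, TAF6, TRA2B, MOB4, TEX14 and LAMB4 lost their shared-spread call. TAF6 also lost it without doxorubicin replicate 1 or doxorubicin replicate 3, LAMB4 without doxorubicin replicate 3, and MOB4 without control replicate 1, doxorubicin replicate 2 or doxorubicin replicate 3.

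**Figure D3:**
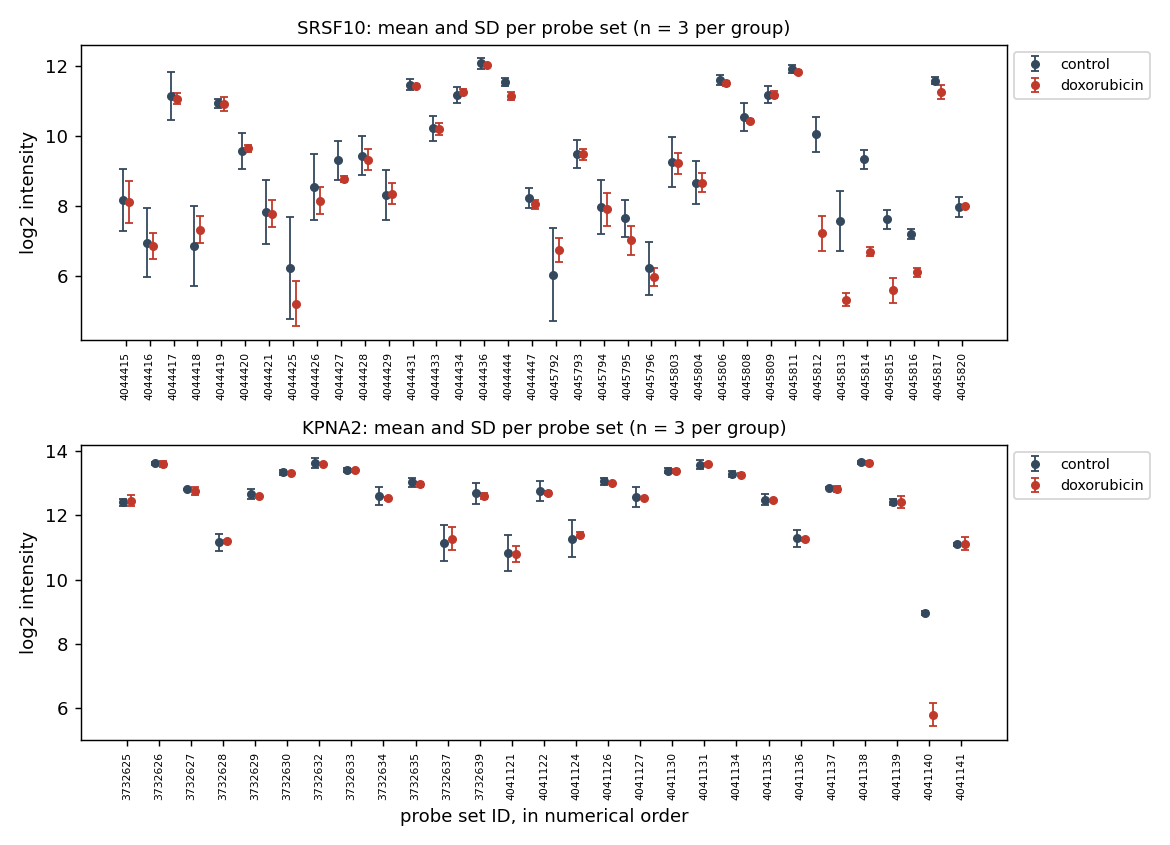
Mean and SD of the log2 intensity of each exon-level probe set (y axis) of SRSF10 and KPNA2 in 3 control and 3 doxorubicin arrays, with probe sets in numerical order of their ID on the x axis. In SRSF10 the drop lies at 4045812 and the next numbers, and in KPNA2 at 4041140 alone, where the mean went from 8.94 to 5.79.

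In total, 351 of 173758 probe sets lost and 104 gained usage with the shared spread, in 367 genes. With the own spread, a test chosen after seeing the data, 87 lost and 13 gained, and 90 of these 100 were among the 455. Simulated data, in which 100 probe sets changed by 1 and 100 by 2 on the log2 scale, gave 213 false calls with the shared spread and 5 with the own spread, so an unknown part of the larger count may be false. Shared-spread calls numbered 202 without control replicate 2, 959 without control replicate 3, 247 without doxorubicin replicate 2 and 240 without doxorubicin replicate 3. Own-spread calls numbered 84, 1 and 31 without control replicates 1, 2 and 3, and 44, 2 and 26 without doxorubicin replicates 1, 2 and 3.

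Gene length was compared because topoisomerases act ahead of the elongating polymerase. The 20% of genes that were longest (2841 genes, median length 164 kb) had a median log2 fold change of 0.03, and the 20% that were shortest (2841 genes, median 3.92 kb) 0.05. Neither class passed camera (p 0.88 and 0.90, and 0.95 and 0.90 with an estimated correlation). In 5 classes of 2841 genes from the shortest to the longest, 81, 57, 29, 25 and 10 genes fell in limma and 14, 9, 17, 14 and 6 rose. The classes also differed in brightness, with median log2 levels of 7.10, 7.61, 7.93, 8.03 and 7.58. Those with levels of 7.61 and 7.58 had 57 and 10 falls, so the median level alone does not order the falls.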

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

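Tests with an offset of 16, with clusters of 1 symbol only, with an estimated correlation after quantile normalization or without each array, with the own spread of each probe set, and of the list excess of usage calls were chosen after seeing the data. Where the cause of a change is not stated, the cause was not tested. Leaving out 1 array at a time gave 248 to 1116 gene-level calls (231 to 1010 falls, 17 to 106 rises), 0 to 705 exon-level calls (0 to 602 falls, 0 to 200 rises), 202 to 959 usage calls (158 to 626 losses, 38 to 333 gains) and 8 to 13 lists. With the replicate number as a block, gene-level calls came to 784, of which 40 rose, exon-level calls to 0 (0 falls, 0 rises), usage calls to 699, of which 175 were gains, and lists to 10. Deviations of same-numbered arrays correlated at 0.30, 0.15 and 0.07 at the gene level and 0.33, 0.10 and 0.03 at the exon level, and not every array correlated best with its own number, so the numbers were not taken to pair the samples. Quantile normalization gave 439 gene-level rises, 18 lists and 1392 exon-level calls with 1152 falls, and median centring 214 gene-level rises and 1401 exon-level calls with 1151 falls. Features at or above the median only, a smaller set, gave 356 gene-level calls (345 falls, 11 rises), 311 exon-level calls (278 falls, 33 rises) and 192 usage calls (159 losses, 33 gains), and no filter on dim probe sets 1133 usage calls (797 losses, 336 gains). Array weights gave 8410 gene-level calls (5131 falls, 3279 rises) and 29548 exon-level calls (15956 falls, 13592 rises); the weight of control replicate 2 was 81.1 against 0.14 to 1.26 for the others at the gene level, so these rest on 1 array. Means of exon-level probe sets per gene gave 128 calls (70 falls, 58 rises), and clusters with 1 symbol only 163 (131 falls, 32 rises). The own spread of each probe set gave 100 usage calls (87 losses, 13 gains) and the splicing index 134, with 58 losses. Under the splicing index, the usage of KPNA2 probe set 4041140 reversed to 0.29 (adjusted p 0.94), because the gene-level value it was set against had itself fallen by 3.45. Lists past the threshold numbered 0 with an estimated correlation and 0 with it after quantile normalization or without any 1 array. A trend in the variance, a threshold of 1.5-fold and an offset of 16 kept every count within 1.5 times. Neither length class passed under any alternative. Among settings of genes, lists and probe sets named singly, 1301 values kept their direction and side of the threshold or were not called in either setting, 328 lost their call and 46 gained one. The planned comparison of 3-prime with 5-prime probe sets and its alternatives were not run, because no order of probe sets in genes was used here. Signal over background limits the dim genes: 730 of the 1059 falls and 80 of the 94 rises lay below the median intensity.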

Other observations

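The splits of the own-spread usage test, the neighbours of fallen genes and every test of an explanation except that of the neighbours of risen genes were chosen after the result was seen.

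Several further gene groups held single changes. Among 24 NF-kB targets, 1 fell: NFKBIA, the inhibitor of that pathway and itself a short-lived transcript, was 2.30-fold lower (limma adjusted p 0.025), and the list median was 0.01; NFKBIA lost its call without any single control array. Of 27 apoptosis regulators, 2 fell, the BH3-only gene BCL2L11 by 1.87-fold and the death receptor adaptor FADD by 1.74-fold (adjusted p 0.015 and 0.042), with a list median of -0.03. Fallen apoptosis regulators numbered 0 without control replicate 1, control replicate 2 or doxorubicin replicate 2 and 1 without each other array; FADD lost its call in every case. The co-chaperone DNAJB1 was 1.95-fold lower (adjusted p 0.026) among 15 heat shock protein genes with a median of 0.01, and kept its call only without doxorubicin replicate 1. None of 26 interferon-stimulated, 21 ribosome biogenesis, 20 ribosomal protein or 15 sterol synthesis genes passed in limma, and their medians were -0.13, -0.12, 0.16 and 0.12. At an unadjusted p under 0.05 these lists held 0 genes, 2 lower, 1 lower with 4 higher, and 2 higher. After median centring the medians of the apoptosis, interferon and ribosome biogenesis lists were 0.12, 0.02 and 0.03, and those of the NF-kB, heat shock, ribosomal protein and sterol lists 0.16, 0.16, 0.31 and 0.28. The interferon median followed single arrays: it was 0.32 without control replicate 1, -0.73 without control replicate 3, -0.60 without doxorubicin replicate 1 and 0.42 without doxorubicin replicate 3, with a camera adjusted p of 0.016 without control replicate 3 and 0.00027 without doxorubicin replicate 1 at the preset correlation, against 0.72 and 0.77 with an estimated one (a correlation of 0.81 with all arrays, the highest of the 25 lists). Ribosome biogenesis genes had a camera adjusted p of 0.021 without control replicate 3, against 0.46 with an estimated correlation. Members with the smallest p were XAF1 at -0.94, POLR1B at -0.76, RPS15A at 0.47 and EBP at 0.46 (adjusted p 0.33, 0.13, 0.10 and 0.12), as were TK1 at 0.43 among G1/S genes, LYZ, too dim for a fold to be given, among white blood cell markers, CDH3 at 0.28 among basal markers and TOP3B at -0.41 among topoisomerases (adjusted p 0.085, 0.12, 0.34 and 0.23). Adjusted over each list alone, the counts were 1 fallen for NF-kB, 2 for apoptosis, 1 for heat shock, 1 risen for fibroblast and 0 for the other lists of this paragraph. None of the NF-kB, apoptosis, heat shock, interferon, ribosome biogenesis, ribosomal protein and sterol lists passed camera with all arrays as deposited (adjusted p 0.43, 0.16, 0.39, 0.26, 0.24, 0.075 and 0.16, and adjusted p 0.72, 0.68, 0.79, 0.83, 0.77, 0.68 and 0.68 with an estimated correlation).

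PPP1R10, picked after its values were seen, was 4.73-fold lower at the gene level (log2 -2.24 ± 0.18 SE, adjusted p 0.0033), with 16 of 27 probe sets lower. Of 4 probe sets that gained usage with the shared spread, whose own log2 fold changes lay between -0.73 and -0.45, 1 passed with the own spread (usage difference 1.22, adjusted p 0.042). Probe sets with changed usage were mostly dim ones: 76.1% of those that lost and 91.3% of those that gained were dimmer than the mean of their gene in control arrays, against 51% of all tested.

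More transcript clusters fell than rose. Falls made up 91.8% of the calls as deposited, 71.2% after quantile normalization and 81.6% after median centring. To account for the whole excess, scaling between arrays would have to bring falls to 50% of the calls. Their lowest share after either rescaling, with all arrays or without any 1, was 63.9%. This argues against scaling as the only cause, and leaves open that part of the excess depends on it. For the 329 falls at or above the median intensity, values near background are argued against as well, since the lowest share there without any 1 array was 94.7%. For the 730 below it they stay open, as each doxorubicin array had at least 197 clusters with an intensity under 1 and no control array more than 106. The gene-level summary of probe sets stays open. Genes taken as means of their exon-level probe sets gave 70 falls among 128 calls, or 54.7% (exact interval 45.7 to 63.5). These means cover only genes with a symbol, whereas 806 of the 1059 falls had none. Clusters with 1 symbol, tested alone, gave 131 falls and 32 rises, or 80.4% falls. Exon-level probe sets gave 694 falls and 217 rises, but 13084 lower and 13266 higher at an unadjusted p under 0.05 in limma. The excess of falls may therefore belong partly to that summary. A general loss of RNA is untested, as array values carry no absolute amount.

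Some dim genes rose in doxorubicin. In the median risen gene 100% of the probe sets were higher, against 61.6% of all probe sets, which argues against a few aberrant probe sets. The gene-level values that picked these genes come from the same arrays, so this agreement is not independent. Scaling of all dim clusters is argued against too, since the 20% of genes dimmest in controls had a median log2 fold change of 0.04. A candidate explanation is transcription that runs into a dim gene from an active neighbour. The brighter adjacent gene of 60 risen genes had a median control log2 level of 9.94, against 8.36 in 10000 random draws of genes matched for their own control level (p 1e-04, one-sided permutation, the smallest these draws can give), and that of 202 fallen genes 8.65 against 8.84 (p 0.94). Adjacent meant next on the chromosome among single-symbol genes found in the RefSeq table. Among these 60 genes, 0 had an adjacent gene that rose at the gene level. SEPTIN4 beside TEX14, KIAA0586 beside TOMM20L and ABCA5 beside ABCA10, picked out after their values were seen, had 7, 1 and 1 risen probe sets. C17orf47, which also rose, was not among the 60 and so could not count as a neighbour. Its cluster number, 3764581, lies near 3764592 of TEX14 and probe set 3764588 of SEPTIN4, so the 0 may be too low. Strand was not used here, and activation of these genes themselves remains open.

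The p53 targets did not pass as a list at 6 hours. Too little precision to see a 2-fold rise of most members is argued against by 31 of 34 genes whose 95% interval excludes it. That count lay between 25 and 31 after either scaling or without any 1 array. A smaller rise of the list is not excluded, since its median was 0.19 after quantile normalization and 0.25 after median centring. With an estimated correlation camera passed 0 lists, so its result carries little weight against such a rise. Lower synthesis of short-lived transcripts, which at this dose could offset induction, is a hypothesis that the data leave open: the 8 immediate early genes that fell, with 0 risen, had been counted before, 24 of 32 did not pass, 0 fell without control replicate 2 and the list median was -0.10 after median centring. Whether p53 itself was active was not analysed here.

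With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. Gene-level calls numbered 1153 in the real split, the 1 split that gave as many, and at most 2 in any other. Exon-level calls numbered 911 against at most 0, reached in 1 split, and usage calls 455 against at most 336, reached in 1 split. With the own spread usage calls numbered 100 against at most 0, also reached in 1. Lists past the threshold numbered 10 in the real split and up to 12 in others, with 3 splits giving as many. Of the 10 lists that passed, the histone, KRAB zinc finger, immediate early and circadian lists had their lowest camera p in the real split (4.24e-29 for histones, against 6.65e-16 in another). Oxidative phosphorylation had 4.73e-06 against 8.43e-12 in another split, G2/M 0.00014 against 1.88e-09 and double-strand break repair 1.17e-06 against 5.46e-09. For the stress response, splicing factor and cleavage lists another split also gave a lower p (0.014 against 7.51e-06, 0.015 against 0.0013 and 0.0038 against 5.26e-05). Counting the real split, a p as low came in 6 of 10 splits for oxidative phosphorylation, 4 for G2/M and 3 for double-strand break repair. For the stress response, splicing factor and cleavage lists it came in 4, 3 and 4. Length classes numbered 0 against at most 2, and all 10 splits gave as many.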
